A study of Arabidopsis thaliana with 6 samples.

How the data were processed

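RNA was extracted from shoots of WT and phod1 seedlings with a plant column kit and DNase treatment, and libraries were made by a standard Illumina protocol, per the labels. The authors deposited a table of estimated counts per gene and sample, in expected counts, with whole numbers that are not normalized and no pooling of samples. The submitters' processing notes name CASAVA 1.4, STAR, StringTie and the genome build TAIR10, and give no role or order for them. The counting command, the annotation, the strand setting and any filter are not given in the sources used here. Values at multiples of 4 were in excess in the table. The value 4 was seen 1703 times against 562 times for 3 and 832 times for 5, so that 1 fragment was taken to be worth 4 units, and floors were set at 3 fragments, or 12 units, per library. That scale is read from the values and not stated by a source. The analysis plan assumed read counts, and the same test was kept for the estimated counts after rounding them to whole numbers, which changed no value. Counts of neighbouring or overlapping gene models can be assigned to 1 of them as a whole, which can move a gene's value in a single library or in all of them.

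The authors also deposited a table of their own comparison of phod1 with WT. Per the file headers it gives a log2 fold change with its standard error, p-values and adjusted p-values, the test score that is the ratio of the fold change to its error, and a mean normalized count, and the tool behind it is not given in the sources used here. The highest adjusted p in the deposited table was 0.04998, so it holds genes under 0.05. With DESeq2 1.42.0 on every gene with a count, 3887 genes passed, all of them in that table, and log2 fold changes differed by at most 5.8e-05. Gene symbols and neighbours came from the reference annotation TAIR10.1, matched by locus identifier, in which 20318 of 21693 identifiers of the count table had a locus, and from the deposited tables otherwise. Its coordinates are not printed, since the build named by the submitters is TAIR10.

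Samples were grouped by the genotype in the labels, as 3 WT and 3 phod1, and all 6 sample columns were used. No 2 libraries held identical values. Of 21693 genes, 7887 were at 0 in every library, and 10803 passed filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, genotype as the only term, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values use the TMM-scaled library sizes, errors are SDs over 3 libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic. The depth of 33183463 to 54720319 units per library puts the floor at 0.256 to 0.404 CPM. A fold against a genotype at 0 in all libraries is a lower bound at that floor, a ratio against 1 to 3 fragments has a 95% exact Poisson counting interval, no ratio is given against less than 1 fragment, and no fold is given where both genotypes are at or under the floor. SHR and PHO1 were also tested by an exact two-sided permutation test of CPM.

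The 27 gene lists were written before the data were examined. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 4) with its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and with an estimated correlation and with fry beside it. With an estimated correlation camera also takes its degrees of freedom from the samples, which are far fewer than the genes it uses with the preset. Fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. For each list the members past the threshold were counted over all genes and adjusted over the list alone. The genes named were also set by a rule before the data were examined. It takes SHR and PHO1, then the 6 largest rises and the 6 largest falls among called genes with no overlap of CPM between genotypes and a mean of at least 1 CPM in the higher one, and the called members of each list with the smallest p. These are up to 6 for phosphate starvation, up to 4 for lipid remodelling and up to 2 for each other list, and a count of 5 or fewer may be named in full. Further members of the cytokinin, clock, sulfur and photosynthesis lists, some of which did not pass, and PHT1;4, SCR, SAG13, GPT2, PCNA1, PIP5K4, UKL4, RBCS1A, ABA4, LHB1B2 and RWA3, were chosen after their values were seen. The share of called genes was compared by Fisher's exact test per chromosome and per window of 1 Mb, over 10641 tested genes with a position.

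The fits were tested on simulated counts for 10652 genes of the phod1 against WT comparison, drawn from the real means, library sizes and the spread of each gene in the fit. The test recovered 34 of 100 genes changed 2-fold (34.0%) and 72 of 98 changed 4-fold (73.5%), and 6 of 112 calls were false (5.36%). These shares depend on the spread used, which differs widely between genes. They also depend on how many genes change, since the Benjamini-Hochberg cut-off is stricter when few do. Far fewer genes were changed here than were called in the data (2988 of 10803), so recovery in the data may differ. A first simulation, drawn with edgeR's gene-wise dispersions, recovered a far smaller share of the 2-fold changes and was replaced after its result was seen. A list changed on purpose was called and 0 of 26 unchanged lists were. Simulated genes were drawn independently of each other, so this does not show how the list test behaves with correlated genes.

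Alternatives set before the data were examined were the size factors of DESeq2 (RLE) or the upper quartile in place of TMM, the DESeq2 Wald test, limma-voom, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate number as a block, a threshold of 0.01, an estimated correlation or fry for the lists, windows of 500 kb, and leaving out each library. Robust dispersion, counts divided by 4, and leaving out genes in which 1 library lay at least 8-fold from both its sister replicates, themselves within 2-fold of each other (on CPM plus 0.5), were chosen after seeing the data.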

Results

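Transcript levels were measured by RNA-seq in shoots of 8-day-old Arabidopsis thaliana seedlings of the wild type (WT) and of the phod1 mutant, with 3 samples of each genotype. Seedlings grew at 23 °C on nutrient-rich agar of 1/2 Murashige and Skoog strength that held 1.0% sucrose and 1.1% agar, with 16 h of light and 8 h of darkness. The title of the study names SHORT-ROOT, PHOSPHATE1 and the allocation of phosphate, and the single comparison of the design asks how the shoot transcriptome of phod1 differs from that of the WT. The labels do not say which gene phod1 affects, so no library could be checked against a targeted gene. Estimated counts summed to 34809021, 54720319 and 34226295 units in WT 1 to 3 and to 33324127, 33183463 and 33932995 units in phod1 1 to 3, with 1 sequenced fragment worth about 4 units by the spacing of the low values. A floor of 3 fragments (12 units) in a library stood at 0.256 to 0.404 CPM, and floors and counting intervals cover counting error only. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Correlations of log2 CPM were 0.945 to 0.951 within a genotype and 0.885 to 0.893 between genotypes, and the first principal component, with 52.6% of the variance, separated the genotypes.

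The phod1 shoots held more transcript of genes of the phosphate starvation response, of lipid remodelling, of anthocyanin synthesis and of the iron and sulfur deficiency responses than WT shoots did. They held less of nuclear photosynthesis genes, of sugar starvation genes and of early touch and wounding genes. Of these groups, the sulfur, photosynthesis and sugar starvation lists lost their call with an estimated correlation (adjusted p = 0.0578, 0.116 and 0.0570). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2988 of 10803 genes tested passed an adjusted p threshold of 0.05, of which 1581 were higher and 1407 lower in phod1. Of these, 1245 differed at least 2-fold, 749 higher and 496 lower. The median log2 fold change over all genes tested was 0.014. The nuclear photosynthesis list took 28.8% to 32.2% of all counts in the WT libraries and 20.2% to 21.98% in the phod1 libraries, and the 10 most abundant genes took 19.7% to 22.4% and 15.3% to 16.6%. The share leaves out models that adjoin photosynthesis genes. RBCS1A, in the list, held more than 1 unit in WT 1 alone (18141 CPM), with 16686 to 21697 CPM on the adjoining ABA4 in the other libraries, and the light-harvesting gene LHB1B2, not in the list, was at 0 in all libraries beside RWA3 at 41047 to 50655 CPM in WT and 19628 to 22984 CPM in phod1. The TMM scaling factors were 0.857 to 0.907 in WT and 1.10 to 1.17 in phod1. Of 27 gene lists fixed before the data were examined, 17 passed limma's camera test with its preset correlation of 0.01. With an estimated correlation, which also leaves the test far fewer degrees of freedom, 5 passed. Those 5 were the phosphate starvation, lipid remodelling, anthocyanin, iron deficiency and touch lists.

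Both genes of the study's title differed between the genotypes. SHR (AT4G37650, on chromosome 4), the GRAS transcription factor SHORT-ROOT, fell from 37.1 ± 1.98 CPM in WT to 28.5 ± 0.877 CPM in phod1 (SD, n = 3 each), a log2 fold change of -0.38 (SE 0.0894, adjusted p = 0.0263). PHO1 (AT3G23430, on chromosome 3), the phosphate exporter that loads phosphate into the xylem, rose 2.99-fold from 11.96 ± 1.21 to 35.7 ± 4.85 CPM, a log2 fold change of 1.58 (SE 0.145, adjusted p = 0.00116). The values of both genes did not overlap between genotypes, and the exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 against 3 samples allow. The call of SHR held without WT 1 (adjusted p = 0.0474) and was lost without any one of the other 5 libraries (adjusted p from 0.0516 to 0.0808), while its log2 fold change stayed between -0.41 and -0.33.

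**Figure D1:**
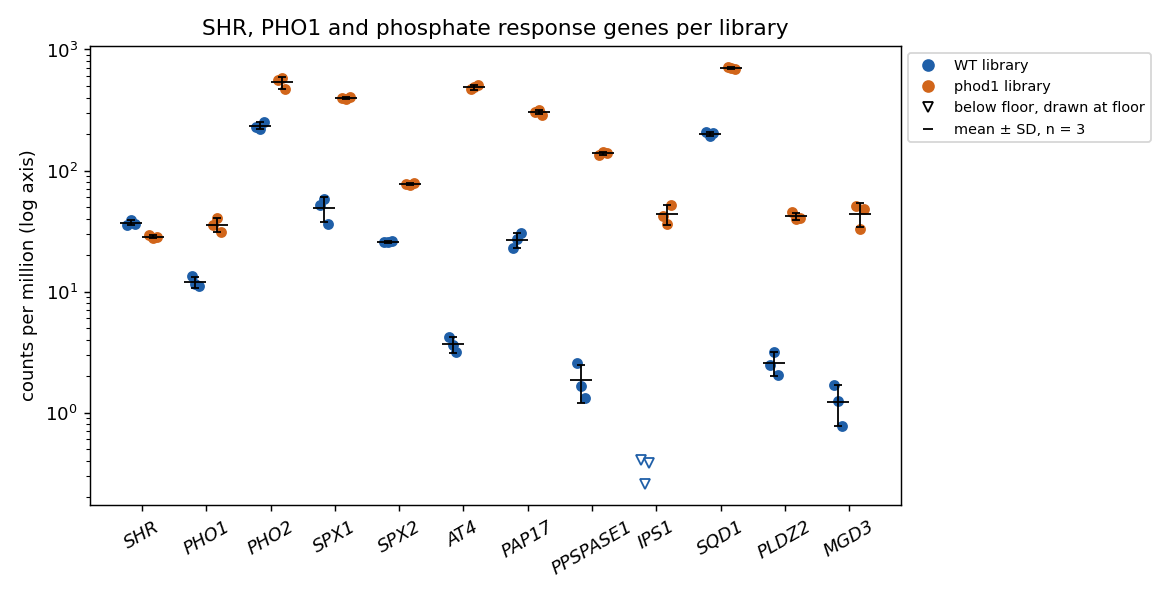
CPM, on a log axis, of SHR, PHO1 and 10 phosphate response genes in WT (blue) and phod1 (orange), with 1 point per library, lines for the mean ± SD (n = 3) and open triangles for IPS1 in WT libraries, which lie below the floor and are drawn at it. PHO1 lies at 11.05 to 13.3 CPM in the WT libraries and at 30.8 to 40.5 CPM in the phod1 libraries, whereas SHR lies at 35.6 to 39.4 and 27.8 to 29.5 CPM.

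Genes known to be induced when phosphate is scarce were higher in phod1, with both genotypes on the same nutrient-rich medium. Of the 25 tested members of the phosphate starvation list, 20 rose, 1 fell and 4 did not pass, and 22 rose and 1 fell when adjusted over the list alone. AT4 (AT5G03545), a non-coding RNA that mimics the target of miR399, rose from 3.67 ± 0.545 to 487 ± 20.4 CPM (log2 7.05, SE 0.155, adjusted p = 3.5e-05). The acid phosphatase gene PAP17 (AT3G17790) rose from 26.7 to 304 CPM (log2 3.51, SE 0.134), the pyrophosphatase gene PPSPASE1 (AT1G73010) from 1.85 to 139 CPM (log2 6.23, SE 0.293), and the phosphate-sensing genes SPX1 (AT5G20150) and SPX2 (AT2G26660) by 3.03 and 1.59 on the log2 scale. The target mimic IPS1 (AT3G09922) had 1 fragment in the WT libraries together and 43.5 ± 8.11 CPM in phod1, a ratio of 1528 with a 95% counting interval of 274 to 60349. The member that fell was LPR1, a ferroxidase gene of the root's response to low phosphate (5.13 to 2.16 CPM, log2 -1.25, SE 0.268). Of the members that did not pass, the phosphate transporter gene PHT1;4 stood at 8.77 ± 1.91 CPM in WT and 93.7 ± 73.8 CPM in phod1, where 1 library lay at least 8-fold from its sister replicates (adjusted p = 0.0521). The list's median log2 fold change was 3.51, or 3.03 with the 5 members at 0 in all WT libraries placed at their bound, and camera gave an adjusted p of 1.1e-13 (adjusted p = 0.0164 with an estimated correlation).

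Genes that replace phospholipids by lipids without phosphorus rose as well. In the lipid remodelling list, 10 of 15 tested members rose, none fell and 5 did not pass, with 10 higher when adjusted over the list alone. SQD1 (AT4G33030), of sulfolipid synthesis, rose from 200 ± 7.60 to 704 ± 13.8 CPM (log2 1.81, SE 0.0648), and the galactolipid synthase gene MGD3 (AT2G11810) from 1.23 ± 0.455 to 43.9 ± 9.66 CPM (log2 5.15, SE 0.360). The phospholipase gene PLDZ2 (AT3G05630) rose by 4.02 and the phosphodiesterase gene GDPD5 (AT1G74210) by 1.76 on the log2 scale. The median was 1.76 and camera gave an adjusted p of 3.7e-05 (adjusted p = 0.0492 with an estimated correlation). The regulators of phosphate transport and signalling went both ways, with 3 of 15 higher, 3 lower and 9 that did not pass. When adjusted over the list alone, 4 were higher and 3 lower. PHO2 (AT2G33770), a ubiquitin-conjugating enzyme gene that restrains phosphate uptake, rose from 235 ± 16.1 to 535 ± 59.4 CPM (log2 1.19, SE 0.109), and PHO1 and the transcription factor gene WRKY6 rose with it. PHR1, the central transcription factor of the phosphate response, fell by 0.64, the ubiquitin ligase gene NLA by 0.72 and the zinc finger gene ZAT6 by 0.60 on the log2 scale. The list's median of -0.11 and mean of 0.063 differed in sign, the direction of the camera test was that of the median, and the test did not pass (adjusted p = 0.899).

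Within the SHORT-ROOT pathway list, 4 of 11 tested members fell, 1 rose and 6 did not pass, and 5 fell and 2 rose when adjusted over the list alone. The members that fell were SHR, its relative SCL23 (AT5G41920; 37.4 ± 1.72 to 14.9 ± 0.635 CPM, log2 -1.33, SE 0.0918), its partner JKD (AT5G03150; 17.5 ± 2.405 to 8.39 ± 1.49 CPM, log2 -1.06, SE 0.181) and the GRAS gene SCL3 (log2 -0.62). MGP, a zinc finger target of SHORT-ROOT, rose from 1.08 to 3.43 CPM (log2 1.65, SE 0.295). SCR, which encodes the partner SCARECROW, had a log2 fold change of -0.40 and did not pass (adjusted p = 0.132). The list's median was -0.40 and camera gave an adjusted p of 0.0414 (adjusted p = 0.152 with an estimated correlation). The call was also lost without WT 3 (adjusted p = 0.0722) and without phod1 3 (adjusted p = 0.0837).

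Cell division genes were lower on balance, with 6 of 25 lower, 2 higher and 17 that did not pass, and 8 lower and 2 higher when adjusted over the list alone. KN (AT1G08560), the syntaxin gene KNOLLE of cytokinesis, fell from 96.0 ± 1.07 to 49.0 ± 3.46 CPM (log2 -0.97, SE 0.0849). The ribonucleotide reductase gene TSO2 (AT3G27060) rose from 128 ± 1.71 to 275 ± 9.63 CPM (log2 1.10, SE 0.0658), and the other member that rose was the replication clamp gene PCNA1 (log2 0.43, adjusted p = 0.0479), which did not pass with the size factors of DESeq2. Camera gave an adjusted p of 0.0175 for the list (adjusted p = 0.117 with an estimated correlation). Of 10 cytokinin response genes, 4 fell, 2 rose and 4 did not pass, and 5 fell and 2 rose when adjusted over the list alone. The response regulator genes ARR9 (AT3G57040; log2 -1.40, SE 0.122), ARR8 (AT2G41310; log2 -0.74, SE 0.1098), ARR5 and ARR15 fell, whereas ARR6 and ARR7 rose. Camera gave an adjusted p of 0.0409 for this list (adjusted p = 0.271 with an estimated correlation), and the call was lost without WT 2 (0.0574), WT 3 (0.0722) or phod1 3 (0.0757).

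Anthocyanin and flavonoid synthesis rose as a group, with 16 of 19 tested members higher, none lower and 3 that did not pass, and 18 higher when adjusted over the list alone. CHS (AT5G13930), chalcone synthase, rose 9.19-fold from 95.1 ± 2.26 to 874 ± 50.6 CPM (log2 3.20, SE 0.0766, adjusted p = 4.5e-05), and GSTF12 (AT5G17220), which carries anthocyanin to the vacuole, from 11.2 ± 1.63 to 197 ± 9.39 CPM (log2 4.14, SE 0.142). The median log2 fold change was 3.28 and camera gave an adjusted p of 5.0e-13 (adjusted p = 0.0164 with an estimated correlation).

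Nuclear photosynthesis genes fell, with 31 of 45 tested members lower, none higher and 14 that did not pass, and 33 lower when adjusted over the list alone. PSAD2 (AT1G03130), of photosystem I, fell from 4696 ± 191 to 1868 ± 74.1 CPM (log2 -1.33, SE 0.0683), and the light-harvesting gene LHCB2.3 (AT3G27690) from 4844 ± 576 to 1478 ± 70.5 CPM (log2 -1.71, SE 0.108). In 5 members that did not pass, LHCA2, LHCB4.1, LHCB5, PSAK and RBCS2B, 1 library lay at least 8-fold from both its sister replicates. All 45 fitted log2 fold changes were negative with a median of -0.92, and camera gave an adjusted p of 1.1e-13 (adjusted p = 0.116 with an estimated correlation). Among genes encoded in the chloroplast, 6 of 80 fell, none rose and 74 did not pass, with 1 lower when adjusted over the list alone. ATPE (ATCG00470) fell from 56.4 ± 4.08 to 28.2 ± 1.46 CPM (log2 -0.999, SE 0.0988). PSBE (ATCG00580) fell from 2.201 ± 0.155 to 1.09 ± 0.141 CPM (log2 -1.01, SE 0.213), and its call was lost without WT 1, WT 3, phod1 2 or phod1 3 (adjusted p from 0.0512 to 0.0644). The median of this list was -0.56 and camera gave an adjusted p of 9.5e-05 (adjusted p = 0.162 with an estimated correlation). Of 23 mitochondria-encoded genes, 22 did not pass, and with adjustment over the list alone none did. NAD5 (ATMG00513) passed over all genes but was at 0 in WT and at 0.349 ± 0.107 CPM in phod1, which is at the floor, so no fold is given. Its call was lost without any one phod1 library (adjusted p from 0.0611 to 0.0813), and camera gave an adjusted p of 0.549 for the list. ATPE and PSBE stood far below PSAD2 and LHCB2.3 in both genotypes. How far the library preparation kept transcripts of organelles was not tested, so these counts may not measure transcript levels there.

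Genes of starch synthesis were among those that rose, and genes known to be repressed by sugar fell. In the sugar and starch list, 7 of 14 members rose, 3 fell and 4 did not pass, with the same counts when adjusted over the list alone. GBSS1 (AT1G32900), granule-bound starch synthase, rose from 59.9 ± 4.89 to 298 ± 2.36 CPM (log2 2.31, SE 0.0876), and APL3 (AT4G39210), of ADP-glucose pyrophosphorylase, from 10.8 ± 1.28 to 79.3 ± 1.95 CPM (log2 2.88, SE 0.122). The members that fell were APL1 (log2 -0.60), PGM1 (log2 -0.74) and SEX1 (log2 -0.92). Camera gave an adjusted p of 0.0414 (adjusted p = 0.152 with an estimated correlation), and the call was lost without WT 3 (0.0897), phod1 1 (0.0587) or phod1 3 (0.0653), and without genes in which 1 library stood apart (0.0715), which leaves out the called member GPT2. All 6 sugar starvation genes fell, over all genes and when adjusted over the list alone. SEN1 (AT4G35770), a dark-induced gene, fell from 54.7 ± 4.51 to 1.38 ± 0.136 CPM (log2 -5.30, SE 0.141), and TPS11 (AT2G18700), of the trehalose phosphate synthase family, from 134 ± 3.47 to 16.9 ± 1.76 CPM (log2 -2.99, SE 0.108). The median was -2.73 and camera gave an adjusted p of 2.7e-06 (adjusted p = 0.0570 with an estimated correlation).

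The iron deficiency response was higher in phod1, with 8 of 9 tested members higher, none lower and 1 that did not pass, and 8 higher when adjusted over the list alone. The transcription factor genes BHLH38 (AT3G56970) and BHLH39 (AT3G56980) were at 0 in every WT library and at 71.5 ± 25.3 and 69.0 ± 2.98 CPM in phod1, at least 205-fold and 198-fold higher against a floor of 3 fragments per library. NAS4 (AT1G56430), nicotianamine synthase, rose from 33.2 ± 3.52 to 208 ± 2.95 CPM (log2 2.65, SE 0.102). The median was 2.65, also with the 2 members at 0 in WT at their bound, and camera gave an adjusted p of 8.6e-08 (adjusted p = 0.0481 with an estimated correlation). In the iron storage list, 3 of 6 members fell and 3 did not pass, with 3 lower when adjusted over the list alone. The ferritin gene FER1 (AT5G01600) fell from 97.1 ± 2.81 to 36.2 ± 3.104 CPM (log2 -1.42, SE 0.0959), NAS3 (AT1G09240) from 41.2 ± 3.73 to 10.01 ± 3.47 CPM (log2 -2.04, SE 0.260) and FER3 by 0.54 on the log2 scale. Camera gave an adjusted p of 0.0152 (adjusted p = 0.117 with an estimated correlation).

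Genes of the sulfur deficiency list rose, with 8 of 13 higher, none lower and 5 that did not pass, and 9 higher and 1 lower when adjusted over the list alone. Whether these members respond to sulfur or to phosphate here was not tested, so their rise does not by itself show a shortage of sulfur. Members of the sulfate transporter family rose in SULTR3;4 (AT3G15990), from 2.18 ± 0.0532 to 28.8 ± 2.54 CPM (log2 3.72, SE 0.118), and in SULTR1;3 (AT1G22150), from 0.357 ± 0.131 to 29.7 ± 1.97 CPM (log2 6.40, SE 0.302). The median was 2.14 and camera gave an adjusted p of 3.4e-04 (adjusted p = 0.0578 with an estimated correlation). In 2 of the sulfur genes that did not pass, LSU1 and APR3, 1 library stood apart from its sisters. Of 10 nitrate genes, 4 rose, 1 fell and 5 did not pass, also when adjusted over the list alone. The transporter gene NRT1.5 (AT1G32450) rose from 14.3 ± 0.175 to 35.7 ± 2.91 CPM (log2 1.32, SE 0.0994), as did NRT1.1, NRT1.8 and NRT3.1, and the nitrate reductase gene NIA1 (AT1G77760) fell from 439 ± 74.0 to 125 ± 8.51 CPM (log2 -1.81, SE 0.145). The nitrate list did not pass camera (adjusted p = 0.0689) except without WT 1 (adjusted p = 0.0341). Of 4 zinc transport genes, ZIP5 (AT1G05300) rose (log2 0.92, SE 0.242, adjusted p = 0.0378), also when adjusted over the list alone, and 3 did not pass. Its call was lost without any one library other than phod1 2 (adjusted p from 0.0571 to 0.105), and camera gave an adjusted p of 0.610 for the list.

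Early touch and wounding genes fell, with 8 of 10 lower, none higher and 2 that did not pass, also when adjusted over the list alone. WRKY33 (AT2G38470), a transcription factor gene of defence, fell from 118 ± 9.42 to 33.9 ± 2.07 CPM (log2 -1.80, SE 0.0999), and CBF2 (AT4G25470), of the cold response, from 40.9 ± 0.898 to 16.5 ± 1.19 CPM (log2 -1.31, SE 0.0964). In both members that did not pass, TCH3 and TCH4, 1 library stood apart from its sisters. The median was -1.48 and camera gave an adjusted p of 2.5e-05 (adjusted p = 0.0492 with an estimated correlation). In the jasmonate list, 8 of 19 rose, none fell and 11 did not pass, also when adjusted over the list alone, with AOC1 (AT3G25760), allene oxide cyclase, at 51.8 ± 1.54 and 281 ± 9.72 CPM (log2 2.44, SE 0.0722) and OPR3 (AT2G06050) at 52.8 ± 2.44 and 95.1 ± 10.12 CPM (log2 0.85, SE 0.106). Camera gave an adjusted p of 0.0246 (adjusted p = 0.117 with an estimated correlation), and the call was lost without WT 1 (0.116), without phod1 1 (0.0635) or with no filter on low counts (0.0651).

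Of 17 salicylate and immunity genes, 5 rose, 3 fell and 9 did not pass, and 7 rose and 3 fell when adjusted over the list alone. The pathogenesis-related genes PR1 (AT2G14610) and PR2 (AT3G57260) rose, PR1 from 0 to 16.8 ± 2.204 CPM, at least 48.1-fold, and PR2 from 0.460 ± 0.174 to 44.5 ± 3.03 CPM (log2 6.61, SE 0.307). WRKY70, CBP60G and PAD4 fell by 1.04, 0.84 and 0.43 on the log2 scale, and the list did not pass camera (adjusted p = 0.257). Of 18 genes of abscisic acid and dehydration, 2 fell, 2 rose and 14 did not pass, also when adjusted over the list alone. NCED3 (AT3G14440), of abscisic acid synthesis, fell from 33.1 ± 2.16 to 8.81 ± 1.27 CPM (log2 -1.91, SE 0.141) and RD26 (AT4G27410) from 17.2 ± 2.59 to 6.09 ± 1.00 CPM (log2 -1.50, SE 0.188), whereas RD22 and HAI2 rose, and camera gave an adjusted p of 0.140. In the senescence list, 2 of 9 fell, 1 rose and 6 did not pass, and 3 fell and 1 rose when adjusted over the list alone. The transcription factor gene NAP (AT1G69490) fell from 28.0 ± 2.98 to 1.34 ± 0.422 CPM (log2 -4.39, SE 0.265) and SAG29 (AT5G13170) by 0.94, SAG13 rose by 3.70 on the log2 scale, and camera gave an adjusted p of 0.257.

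Clock genes went both ways, with 6 of 14 lower, 2 higher and 6 that did not pass, also when adjusted over the list alone. PRR5 (AT5G24470) fell from 96.1 ± 5.13 to 33.02 ± 2.302 CPM (log2 -1.54, SE 0.0944) and RVE1 (AT5G17300) from 28.8 ± 2.68 to 5.39 ± 1.51 CPM (log2 -2.42, SE 0.224), whereas LHY and RVE8 rose. Camera gave an adjusted p of 0.0175 (adjusted p = 0.117 with an estimated correlation), and the labels used here give no time of harvest. Of 6 heat shock genes, HSP90.1 (AT5G52640) rose from 13.4 ± 2.54 to 20.4 ± 2.28 CPM (log2 0.61, SE 0.173, adjusted p = 0.0482), 5 did not pass, and none passed when adjusted over the list alone. The HSP90.1 call was lost without any one library other than WT 2 (adjusted p from 0.0689 to 0.132) and with the size factors of DESeq2 (0.0508). For the heat list the median was -0.0049, the mean 0.047 and the direction of the camera test upward, with an adjusted p of 0.899, and the median was 0.011 with upper-quartile scaling.

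Markers of other tissues were examined beside these groups. Of 21 root markers 9 had enough counts to be tested, and FRO2 (AT1G01580; 2.21 ± 0.247 to 7.76 ± 1.53 CPM, log2 1.81, SE 0.202) and IRT1 (AT4G19690; 0 to 1.06 ± 0.339 CPM, at least 3.04-fold) rose. Both are genes of iron uptake, and the other 7 root markers did not pass. Over the 9 tested, the median log2 fold change was 1.13 and 6 were positive. When adjusted over the list alone, 2 root markers rose and 1 fell, and camera gave an adjusted p of 0.206. Of 11 seed storage protein genes 2 could be tested, of which CRC (AT4G28520), a cruciferin, passed, with 0 in WT and 0.495 ± 0.189 CPM in phod1, at least 1.42-fold higher. Both passed when adjusted over the list alone, the list's median was 5.33 as fitted and 1.98 with CRC at its bound, and camera gave an adjusted p of 0.0414 (adjusted p = 0.160 with an estimated correlation). The call of CRC was lost without phod1 1 (0.0666) or phod1 2 (0.0585), and that of the list without WT 2 (0.0628), WT 3 (0.0722) or phod1 1 (0.0587). Of 8 vascular genes, the xylem protease gene XCP1 (AT4G35350) fell from 22.5 ± 4.05 to 10.04 ± 1.03 CPM (log2 -1.16, SE 0.17), the phloem lectin gene PP2A1 (AT4G19840) rose from 161 ± 13.5 to 252 ± 27.3 CPM (log2 0.64, SE 0.113) and 6 did not pass, with 3 lower and 1 higher when adjusted over the list alone and a camera adjusted p of 0.227.

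**Figure D2:**
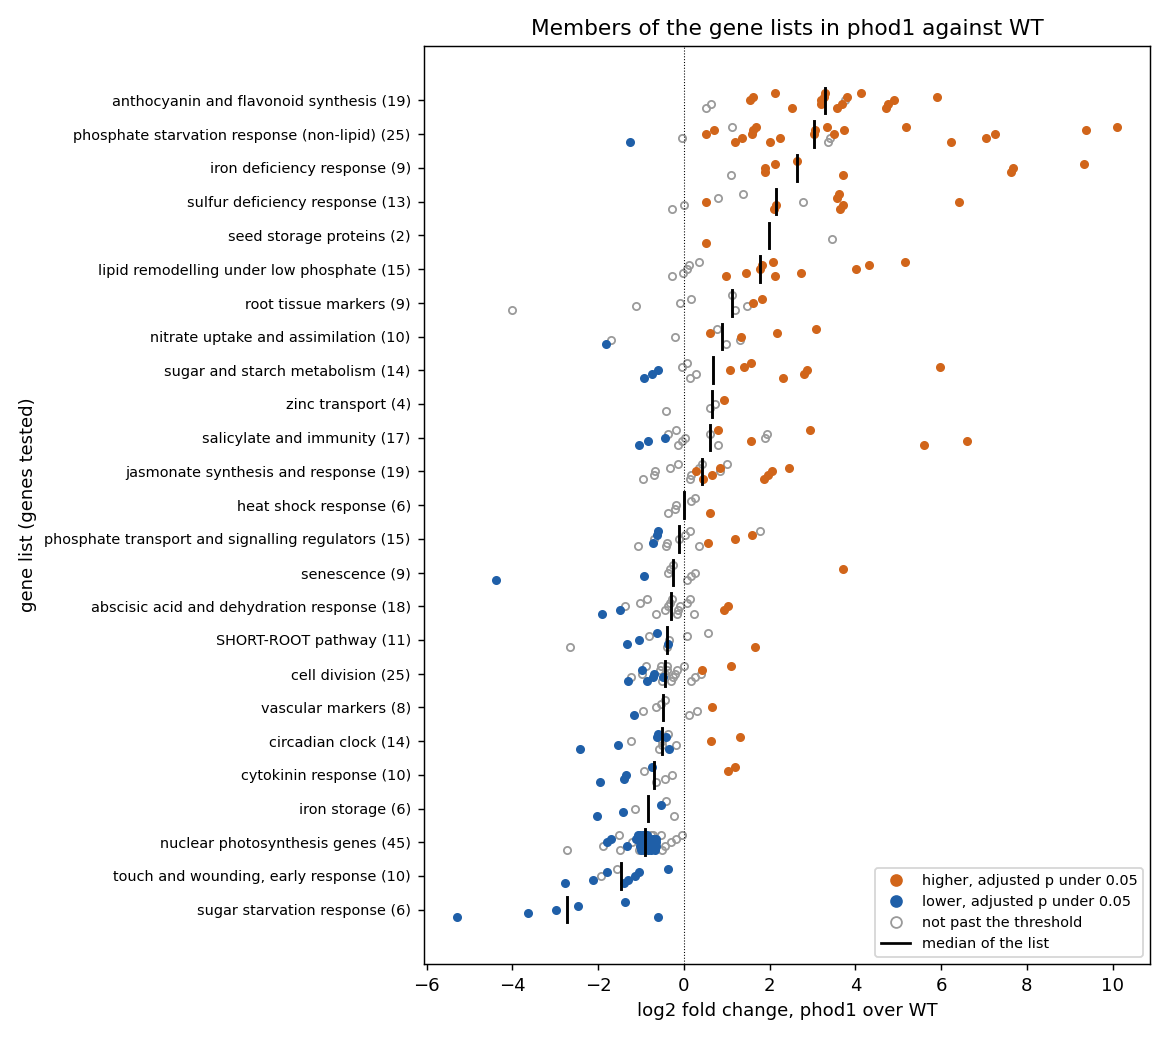
Log2 fold change, phod1 against WT, of the tested members of the gene lists, with 1 point per gene (orange for higher and blue for lower past the threshold, open for not passed) and a black line at each list median. Genes at 0 in all libraries of a genotype are drawn at their bound and the chloroplast and mitochondria lists are not drawn; list medians range from -2.73 for sugar starvation to 3.28 for anthocyanin synthesis, with 3.03 for phosphate starvation at its bound.

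Among genes whose libraries did not overlap between genotypes, which chance gives for 10% of genes with 3 against 3, the largest fitted rises were those of BHLH38, BHLH39, CPSUFE, PR1, AT4G36430 and GSTU2. AT4G36430 and the glutathione transferase gene GSTU2 (AT2G29480) were at 0 in WT and at 15.1 ± 1.19 and 14.0 ± 0.901 CPM in phod1, at least 43.3-fold and 40.2-fold higher. CPSUFE (AT4G26500) had 1 unit in the WT libraries together, less than the 4 units of 1 fragment, and 81.6 ± 8.19 CPM in phod1, so no ratio is given. It overlaps the annotated model of UKL4 (AT4G26510), which went the other way, from 2120 ± 218 to 344 ± 10.2 CPM. How reads were divided between these models is not given in the sources used here. The largest fitted falls were to 0 in all phod1 libraries. PRA1.F1 (AT1G17700), from 10.9 ± 2.05 CPM, was at least 34.6-fold lower and adjoins another gene model that is not analysed here. The terpene synthase gene TPS03 (AT4G16740), from 5.18 ± 2.34 CPM, was at least 16.5-fold lower, and SCRL22 (AT4G33465), from 3.55 ± 0.510 CPM, at least 11.3-fold. AT4G11290, AT2G21990 and AT2G31945 were at least 7.32-fold, 6.05-fold and 4.49-fold lower. Of the 67 named genes, 64 matched a locus of the annotation and 22 of these overlap another annotated gene, BHLH38 (with PIP5K4), CHS, PAP17, PLDZ2, GDPD5, SULTR3;4 and LHCB2.3 among them. Others, PHO1, AT4, IPS1, SPX1, PHO2 and SEN1 among them, overlap no gene but lie within 200 bp of one. The counts of overlapping and adjoining genes are uncertain to that extent, as are those of close paralogs such as the LHCB2, GSTU and AOC genes.

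The authors' deposited table lists 3902 genes, 1990 higher and 1912 lower in phod1, of which 1604 differed at least 2-fold. All 2988 genes called by edgeR's quasi-likelihood test were in it with the same direction, and of the 1245 called at least 2-fold, 1241 were among its 2-fold genes. Of its genes, 914 were not called by edgeR, 130 of which had too few counts to be tested. In the authors' deposited table SHR had a log2 fold change of -0.39 (SE 0.0979) and PHO1 of 1.57 (SE 0.174). Called genes were not concentrated on a chromosome or in a window by Fisher's exact test. The share of tested genes called was 27.4% to 28.9% per chromosome (smallest adjusted p = 0.881), and 0 of 121 windows of 1 Mb passed (smallest adjusted p = 0.769), with 4 at an unadjusted p under 0.05.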

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

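The fits with robust dispersion, with counts divided by 4 and without genes in which 1 library stood apart were chosen after seeing the data. The count of 2988 genes stayed between 2128 and 3872 under all settings but 2. It was 1466 at an adjusted p threshold of 0.01, which is stricter by construction, and 1500 with the replicate number as a block. Of these 1500 genes 1471 were shared with the 2988, all in the same direction. The numbers are not said to pair the samples, and correlations of deviations of same-numbered samples were -0.0059, -0.051 and 0.0074, with 0 of 6 samples closest to its own number in the other genotype, a hint from the data and not the design. The block also ended the calls of 11 of 65 further named genes. The count of genes at least 2-fold changed ranged from 883 to 1493 around 1245. All 16 settings with a count of shared genes kept the direction of every shared call. PHO1 kept its direction and call under every alternative run, with log2 fold changes of 1.48 to 1.67 without 1 library. SHR kept its direction, at -0.41 to -0.33 without 1 library and at -0.38 with the block (adjusted p = 0.109), where its call was lost; the cause was not tested, although these fits have fewer samples or degrees of freedom. Of 585 checks of 65 further named genes, 554 kept direction and call, 31 lost the call and 0 reversed, and 54 genes kept both throughout. These genes were picked as called ones from the same libraries, so most of this retention is built in and is no separate evidence. Lists that passed fell from 17 to 5 with an estimated correlation and were 22 with fry. Among lists that lost the call, the estimate exceeded the preset 0.01 for photosynthesis (0.176), sugar starvation (0.088), cytokinin (0.134) and chloroplast genes (0.0722). For the others, such as the SHORT-ROOT list (-0.0028), it was below 0.01, so a higher correlation does not account for their loss. With an estimate, camera also uses far fewer degrees of freedom, which raises p-values by itself. The phosphate starvation list, at an estimate of -0.0079, went from a camera adjusted p of 1.1e-13 to 0.0164. The SHORT-ROOT list had an adjusted p of 0.152 with the estimated correlation, 0.0564 with the block and 0.0341 to 0.0837 without 1 library. The cause of its losses with the block or without 1 library was not tested. The block also ended the call of the sugar and starch list (0.0564), and the phosphate starvation and lipid lists passed under every alternative. Windows of 500 kb gave 0 of 234 past the threshold, with 16 at an unadjusted p under 0.05. Depth limits genes near 0.256 to 0.404 CPM such as CRC and NAD5.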

Other observations

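The tests of gene families, of genes in which 1 library stood apart by counting noise or by library, of root tissue and of the time of harvest were chosen only after the results were seen; the test of adjoining gene models and the count of splits were set before. Genes were grouped by the stem of their symbol into 129 families of at least 10 tested members, and Fisher's exact test with Benjamini-Hochberg adjustment over 258 tests found 8 stems enriched among genes higher in phod1 and 6 among genes lower, against 14.6% higher and 13.0% lower over all genes. Fisher's test treats genes as independent, although members of a stem can move together. These p-values therefore do not measure the spread between samples. Glycosyltransferase (UGT) genes rose in 21 of 47 members and fell in 1 (adjusted p = 1.8e-04), and glutathione transferase genes in 10 of 21 of the GSTU class, where 1 fell (adjusted p = 0.0106) and 6 of 11 of the GSTF class (adjusted p = 0.0427). GSTF6 rose from 8.96 ± 1.98 to 441 ± 22.8 CPM (log2 5.62, SE 0.201) and GSTU1 from 2.90 ± 0.488 to 32.3 ± 2.86 CPM (log2 3.48, SE 0.167). Some UGT and GSTF members, such as GSTF12, also belong to the anthocyanin list. Genes of the ribosomal protein stem RPL rose in 14 of 30 members and fell in 5 (adjusted p for higher = 0.0024), with RPL12C at 75.5 ± 2.69 and 156 ± 13.3 CPM (log2 1.05). The symbol RPL4 occurs among both the higher and the lower members. The stem RPS, which also holds ribosomal protein genes, rose in 8 of 25 members, fell in 1 and did not pass (adjusted p for higher = 0.250). Genes of the mitochondrial import machinery (TIM) rose in 7 of 12 members (adjusted p = 0.0164), with TIM13 at 9.16 ± 0.867 and 23.1 ± 1.59 CPM (log2 1.33), and chaperone (HSP) genes in 9 of 17 (adjusted p = 0.010), with HSP60 at 19.98 ± 0.436 and 41.7 ± 0.550 CPM (log2 1.06). The other stems higher were PHT, with 8 of 14 and 1 lower (adjusted p = 0.010), and the receptor-like kinases CRK, with 12 of 34 and 5 lower (adjusted p = 0.0427).

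Genes of the stem ERF, which includes ethylene response factors but is set by symbol alone, fell in 10 of 21 members and rose in 2 (adjusted p for lower = 0.0063). ERF6 fell from 88.5 ± 1.58 to 10.5 ± 1.16 CPM (log2 -3.07, SE 0.117) and ERF5 from 55.6 ± 1.34 to 11.2 ± 0.764 CPM (log2 -2.31, SE 0.0975). Genes of the stem SAUR, also set by symbol alone, fell in 10 of 19 members and rose in 5 (adjusted p for lower = 0.0027), with SAUR22 at 12.1 ± 0.215 and 3.04 ± 0.441 CPM (log2 -1.998). The symbol SAUR21 occurs among both the higher and the lower members. LBD genes fell in 7 of 15 and rose in 1 (adjusted p = 0.0364), among them LBD38 (log2 -1.08) and LBD39 (log2 -0.90), which repress anthocyanin genes and respond to nitrate. The other stems lower were LHCB, with 9 of 12 (adjusted p = 2.1e-04), RTFL, with 6 of 12 (adjusted p = 0.0427), and CAT, with 6 of 10 and 1 higher (adjusted p = 0.0164), a stem that mixes catalases and amino acid transporters. The directions held with RLE and upper-quartile scaling. The smallest p-values of all genes were those of EARLI1, from 2.44 ± 0.131 to 198 ± 6.72 CPM (log2 6.34), BGLU11, from 1.84 ± 0.0916 to 80.6 ± 2.45 CPM (log2 5.45), and HSPRO2, from 757 ± 25.7 to 73.4 ± 3.14 CPM (log2 -3.37). The anthocyanin repressor gene MYBL2 fell from 251 ± 12.4 to 40.5 ± 2.49 CPM (log2 -2.63, SE 0.0872). The 3 genes with the smallest p, MYBL2 and the family examples were chosen after their values were seen. Of the 10 splits of the 6 samples into 3 and 3, which are too few for a share under 0.05, the real one called 2988 genes and the highest other 3, and 1 split called as many as the real one, itself.

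In 272 genes (2.52% of those tested) 1 library lay at least 8-fold from both its sister replicates, far below them in 223 genes, and 5 of the 272 were called (1.84%, against 28.3% of other genes). LHCB4.1 stood at 17.2 CPM in WT 1 and at 14668 and 14184 CPM in the other WT libraries. A single poor library is argued against, since no library held more than 18.5% of the cases. By an exact binomial test of the library against its sisters in fragments, 303 of 303 cases (100%) lay beyond counting noise. The largest p was 3.2e-09 after Bonferroni adjustment over 64818 tests. The 8-fold rule that picked the cases admits only differences too large for counting noise. The outcome of this test was therefore set in advance and is no separate evidence. Reads assigned as a whole to an overlapping or adjoining gene model may account for some cases: RBCS1A had 538966 units in WT 1 and 0 or 1 in the others, while the adjoining ABA4 had 851 in WT 1 and 638007 to 1016782 in the others, and in 7 of 302 cases a neighbour moved the other way in the same library (0 in another library of that genotype). These 7 are ABA4 itself and both members of the pairs AT1G10150 and AT1G10155, EGY3 and BTF3, and AT4G16500 and RGF6. Such assignment of reads cannot be told apart from other sources for the rest, since genes near another model were not clearly more frequent among them (odds ratio 1.10, 95% interval 0.857 to 1.42 by the Cochran-Mantel-Haenszel test), and no biological explanation was tested.

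The rise of iron deficiency genes (8 of 9) came with IRT1 and FRO2, which are root markers as well as iron genes, so root tissue in the phod1 shoot samples was weighed. Of the other 7 root markers tested, 0 were called higher or lower by edgeR's test, and 4 had a positive fitted log2 fold change. THAH, THAS and CASP1 stood at 1.48, 1.197 and 1.13 (adjusted p = 0.0959, 0.176 and 0.545), whereas RCI3 and RHD2 stood at -4.02 and -1.12 (adjusted p = 0.0552 and 0.306) and THAD at -0.09 (adjusted p = 0.906), all below 2 CPM in both genotypes. PYK10, at 220 ± 14.5 CPM in WT and 245 ± 27.6 CPM in phod1 (log2 0.16), is too abundant in WT to show a small share of root. Root tissue and a response of the mutant shoot to iron or phosphate supply cannot be told apart from these values, since the remaining root markers have few counts and go both ways.

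Clock genes may have differed because samples were taken at another time of day. Among the genes with a peak near dawn, LHY and RVE8 were higher (log2 1.31 and 0.63) and RVE1 lower (log2 -2.42), 1 gene that moved against the other called ones. This split rests on 1 gene and on a rule set after the results were seen, so it does not decide on harvest time. CCA1, which peaks with LHY, had a log2 fold change of -0.37 (95% interval -1.23 to 0.49) against 1.00 to 1.62 for LHY. For genes with a later peak, 4 of 8 were called lower and 0 higher by edgeR's test, with all 8 fitted log2 fold changes negative, and a difference in harvest time cannot be told apart from an effect of the genotype, since no harvest times are given in the labels.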
